A study of Mus musculus with 49 samples.

How the data were processed

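Whole ankle, cells from synovial fluid and peripheral blood leukocytes were profiled on Affymetrix mouse expression arrays over a time course of arthritis induced by transfer of K/BxN serum. Serum of K/BxN mice carries autoantibodies, and its transfer into healthy mice causes joint inflammation. The labels give male B6 recipients of 6 weeks and the day after the first serum injection. The value of each probe set is an intensity on the linear scale that the authors obtained by RMA, which corrects background, quantile normalizes the arrays and summarises the probes of each probe set. RMA is named in the submitters' processing notes, and its version is not given in the sources used here. All 49 arrays were present in the table, which held 12488 probe sets and 0 missing values. Array medians lay between 58.6 and 64.1 in ankle, 57.7 and 62.7 in fluid and 58.9 and 62.8 in blood, and 0 pairs of arrays were identical. Replicates of a group correlated across probe sets at r from 0.941 to 0.995.

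The labels describe preparations that differed between and within tissues. For ankle, the sample descriptions give an SDS and urea extraction, while the extraction protocol field names Trizol for all samples. Ankle RNA went through 2 rounds of in vitro amplification. Most fluid samples were taken during dissection, day 3 replicate 1 and day 7 replicate 1 were washed out of dissected ankles, and day 7 replicate 4 and day 18 replicate 3 carry another description with 2 rounds of amplification. Blood leukocytes were taken after lysis of red cells, and blood day 3 replicate 3 also carries another description. Tissue and preparation cannot be separated in comparisons between tissues. The description of ankle day 0 replicate 2 opens with a short name that differs from its title, and its other labels place it at day 0. Only the blood samples are called biological replicates in the labels. For the rest nothing says whether replicates came from separate animals, and p-values then measure the spread between these samples, which may be technical.

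Probe sets were joined to gene symbols through the platform annotation and gene IDs through a RefSeq gene table of assembly GRCm38.p6, used for names only. Of the 12488 probe sets, 10855 had 1 symbol, 396 had several, and 1237 had none or were among the 66 control probe sets. For 16 probe sets the gene ID was not in the current table, and 0 symbols changed. Each of the 8252 genes was represented by its probe set with the highest mean over the 49 arrays, and 2076 genes had more than 1 probe set. Signal over background was judged from 34 negative control probe sets, whose log2 values had a median of 4.40 and a 95th percentile of 6.85. The number of arrays limits the precision of every value.

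Values were put on the log2 scale and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with 1 mean per tissue and day and equal array weights. Ankle, blood and fluid were fitted separately, and comparisons between tissues used the arrays of both. The 17 comparisons, their tests and the gene lists were fixed before the data were examined. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 8252 genes of a comparison, with a threshold of 0.05. Differences are given on the log2 scale ± the standard error from limma. The comparison of fluid with blood or ankle is the mean of the day-matched differences at days 3, 7, 12 and 18. The difference between the ankle and the blood response was tested as an interaction.

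Genes in 27 lists were counted by the same test, over all genes and adjusted over the list alone. Each list was also tested against all other genes with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, with adjustment over the 27 lists. Genes named in the text followed a rule. It took Cxcr2 and its measured ligands in every comparison, the 6 genes with the largest rise and the 6 with the largest fall past the threshold whose arrays did not overlap, and up to 4 members with the smallest p of each list described. Members past the threshold against the direction of their list were named too. Where fewer are named, genes called in every fit that left out 1 array come first. Of 317 named genes past the threshold between 2 groups or tissues, 300 had every array on the side of the change, partly by this rule.

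The procedure was tested on simulated data with 200 changed genes per comparison. It recovered 95% to 100% of those with a log2 change of 2 and 62% to 99% of those with 1. False calls made up 0.6% to 7.9% of the calls. Rates may differ where genes vary together, as in blood.

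Alternatives listed before the data were examined were quantile normalization anew within a tissue, centring of each array on its median, leaving out the genes in the lowest 0.333 of mean signal, a floor at the 20th percentile, the mean of all probe sets of a gene, array weights, robust eBayes, a fit of all 49 arrays together, a minimum change of 2-fold, the replicate number as a block, leaving out arrays of another preparation and leaving out each array in turn. Where this left a group with a single array, that array was assumed to vary like the others. A beta-actin 3' to 5' ratio as covariate, leaving out 4 ankle arrays with liver transcripts, leaving out 2 blood arrays and leaving out the 4 fluid arrays not taken as the rest during dissection were added after seeing the data. Replicate numbers were taken to pair samples where a comparison had at least 3 pairs and the deviations from the group means of every pair correlated above 0.1 across genes. Of 14 comparisons within a tissue, 4 met this, with r from 0.20 to 0.54 for ankle day 3 against day 0, 0.49 to 0.61 for blood day 1, 0.17 to 0.46 for blood day 3 and 0.53 to 0.68 for fluid day 7 against day 3. The 2 pairs of ankle day 1 were too few to judge, although they correlated at 0.71 and 0.73. Other splits of the samples, at most 100 per comparison, were counted for groups of at least 3 arrays.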

Results

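The series followed mice through arthritis induced by K/BxN serum with 49 arrays, 1 per sample, in 16 groups of tissue and day. Whole ankle was sampled before serum, at day 0 (4 arrays), and at day 1 (2), day 3 (3), day 7 (4), day 12 (3) and day 18 (3). Cells of the synovial fluid, which fills the joint space, were sampled at day 3 (3), day 7 (4), day 12 (3) and day 18 (3). Leukocytes of peripheral blood were sampled at days 0, 1, 3, 7 and 12 (3 each) and at day 18 (2). The median intensity of an array lay between 57.7 and 64.1. Of 8252 genes, 4003 (48.5%) had no group mean above the 95th percentile of the negative controls, 6.85 on the log2 scale, so that their differences were measured close to background. A fold is given only where the group means on both sides lay above this level, and a difference from a group mean under it is at best a lower bound in size.

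The title of the series concerns CXCR2, a receptor through which neutrophils follow CXC chemokines into tissue, and its gene and ligands are given in every comparison. Cxcl1, Cxcl2 and Cxcl5 were measured, which are 3 of the 6 ligand genes considered, while Cxcl3, Ppbp, Cxcl15 and the related receptor gene Cxcr1 were not analysed here. Cxcl1 in ankle had a mean log2 intensity of 6.01 at day 0, 7.81 at day 3, 8.91 at day 7, 8.95 at day 12 and 8.10 at day 18. In fluid cells Cxcl2 stood at 9.86 on day 3, 9.12 on day 7, 10.14 on day 12 and 9.97 on day 18. In blood Cxcl5 stayed at or under 4.50, within the range of the negative controls. The group means of Cxcr2 lay between 3.72 and 5.23 in all 3 tissues, below the 95th percentile of the negative controls.

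**Figure D1:**
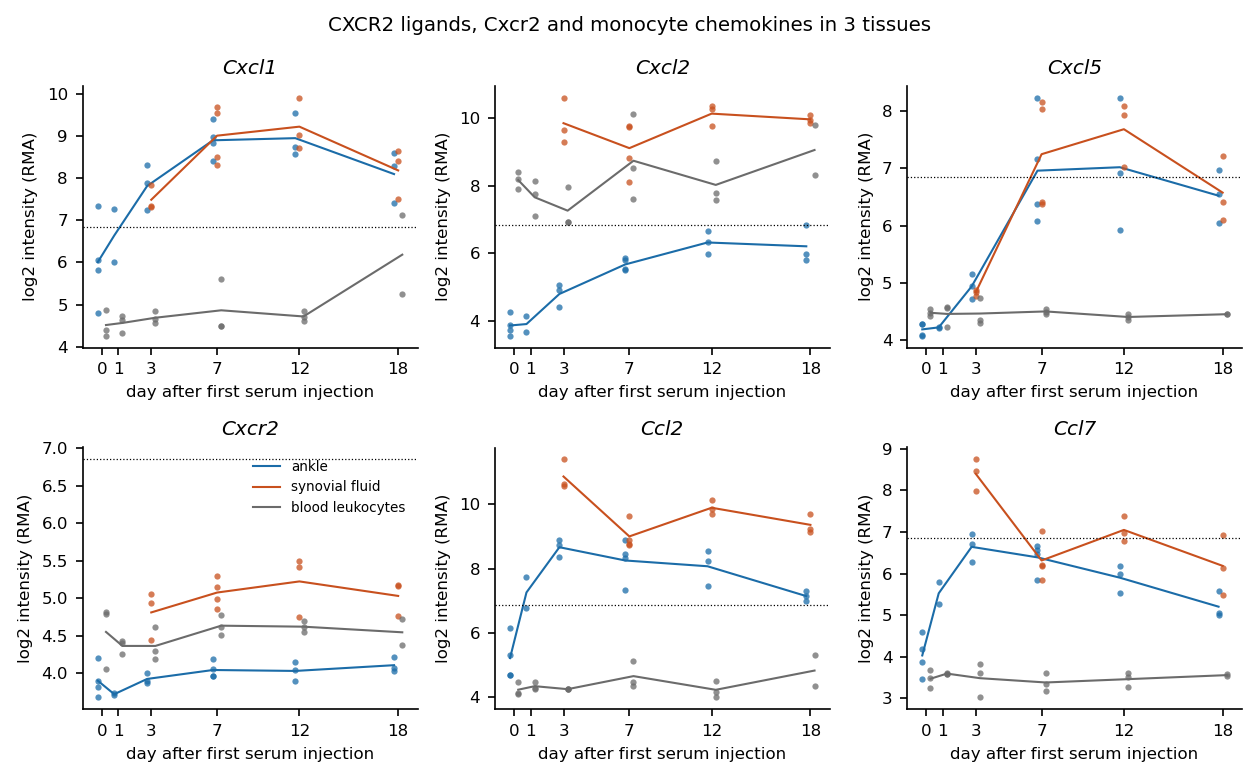
Log2 intensity (RMA, vertical axis) of Cxcl1, Cxcl2, Cxcl5, Cxcr2, Ccl2 and Ccl7 on each array by day after the first serum injection (horizontal axis) in ankle, fluid cells and blood, with lines through the group means and a dotted line at the 95th percentile of the negative controls (6.85). Ccl2 in ankle went from a mean of 5.21 at day 0 to 8.66 at day 3, while Cxcr2 had group means of at most 5.23.

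The ankle comparisons ask how joint tissue changed after serum. Liver transcripts were present in 4 ankle arrays, replicate 1 of days 0, 1, 7 and 12, where albumin (Alb) stood at log2 8.95, 6.39, 8.41 and 10.65, against at most 5.19 in the other 15 ankle arrays. The log2 ratio of the 3' to the 5' beta-actin control, a measure of RNA length, lay between 2.73 and 3.50 in the day 0 arrays and between 3.15 and 4.25 in the later ankle arrays. Both facts accompany every ankle result that follows. As an alternative chosen after seeing the data, leaving out the arrays with liver transcripts gave 48 changed genes at day 3, 607 at day 7, 381 at day 12 and 197 at day 18. With the beta-actin ratio as a covariate, also chosen after seeing the data, the counts were 6, 249, 95 and 104 at these days.

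At day 1 the monocyte attractants Ccl2 and Ccl7 had the largest differences among the chemokines, although no single gene passed the test. Ccl2 differed by 2.05 ± 0.43 and Ccl7 by 1.49 ± 0.30 (2 arrays against 4, both adjusted p = 0.398). As a group, CC chemokines, which attract mainly monocytes and lymphocytes, were shifted upward (camera adjusted p = 3.83e-05), with 0 of 14 measured members past the threshold over all genes and 2 adjusted over the list alone. The mature neutrophil list was also shifted upward (camera adjusted p = 0.00227), with 0 of 12 members past the threshold by either adjustment, and this call was lost (adjusted p = 0.304 with an estimated correlation). Its member Clec4d differed by 0.76. Cxcl1 differed by 0.64 ± 0.54, Cxcl2 by 0.04, Cxcl5 by 0.04 and Cxcr2 by -0.18 (all adjusted p = 0.999), and the CXCR2 ligand list did not pass (camera adjusted p = 0.426, 0 of 3 members by either adjustment). In limma 0 of 8252 genes passed, with 150 at an unadjusted p under 0.05. Without day 0 replicate 2, Ccl2 and Ccl7 passed (both adjusted p = 0.0495) among 4 genes.

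At day 3 Saa3, an inducible serum amyloid A of inflamed tissue, rose by 4.72 ± 0.35 (adjusted p = 9.16e-07, 3 arrays against 4). Ccl2 rose by 3.45 ± 0.38 (adjusted p = 9.86e-05) and Ccl7 by 2.61 ± 0.26 (adjusted p = 4.58e-05). The day 0 means of these genes, 6.14, 5.21 and 4.03, lay within the range of the negative controls, so that the rises are at best lower bounds, and Ccl7 was still within it at day 3 (6.64). Clec4d, a C-type lectin of myeloid cells, rose by 2.25 ± 0.30 (adjusted p = 0.00109), and Mmp3, the matrix protease stromelysin 1, by 1.99 ± 0.29 (3.98-fold, adjusted p = 0.00263). Cxcl1 differed by 1.81 ± 0.47 and Cxcl2 by 0.93 ± 0.24 (both adjusted p = 0.131), Cxcl5 by 0.75 (adjusted p = 0.742) and Cxcr2 by 0.02 (adjusted p = 0.991). Without day 0 replicate 4, Cxcl1 passed (adjusted p = 0.0381).

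Among gene groups at day 3, CC chemokines were shifted upward (camera adjusted p = 1.01e-08), with 3 of 14 members risen over all genes and 5 adjusted over the list alone. The CXCR2 ligands were shifted as a group (camera adjusted p = 0.000139), with 0 of 3 over all genes and 2 adjusted over the list alone. Mature neutrophil genes were shifted upward too (camera adjusted p = 1.01e-08), with 1 of 12 risen and 5 adjusted over the list alone. S100a8 differed by 1.12 (adjusted p = 0.113), and passed without day 0 replicate 2 (adjusted p = 0.0247). Monocyte and macrophage genes were shifted (camera adjusted p = 0.000167, 2 of 13 risen, 4 adjusted over the list alone), but not by the other test (adjusted p = 0.13 with an estimated correlation). Its scavenger receptor gene Msr1 rose by 1.11 (adjusted p = 0.00865), a call lost without day 3 replicate 1 (adjusted p = 0.114), while its other probe set differed by 0.08. Proliferation genes were shifted upward (camera adjusted p = 6.9e-07, 0 of 12 over all genes, 4 adjusted over the list alone), again not by the other test (adjusted p = 0.121 with an estimated correlation), and Top2a differed by 0.89 (adjusted p = 0.136). Skeletal muscle genes were shifted downward (camera adjusted p = 0.00841, 0 of 13 by either adjustment, median -0.90), which was lost as well (adjusted p = 0.531 with an estimated correlation), and Acta1 differed by -1.25 (adjusted p = 0.531). In all, 15 genes were higher and 4 lower than at day 0, and none of the 4 kept its call in every fit that left out 1 array. The count of 19 moved to 44 without day 0 replicate 2, to 9 without day 0 replicate 3 and to 6 without day 3 replicate 1.

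At day 7 the response was broad, with 255 genes higher and 300 lower than before serum (4 arrays each). Saa3 rose by 5.76 ± 0.33 (adjusted p = 9.59e-09), at best a lower bound given its day 0 mean of 6.14. All 3 measured CXCR2 ligands rose, Cxcl1 by 2.90 ± 0.44 (adjusted p = 0.000472), Cxcl5 by 2.77 ± 0.42 (adjusted p = 0.00047) and Cxcl2 by 1.81 ± 0.22 (adjusted p = 6.07e-05). Cxcl2 in ankle had group means between 3.87 and 6.32, within the range of the negative controls at every day, while Cxcl1 and Cxcl5 started within it (6.01 and 4.19) and stood above it at day 7 (8.91 and 6.96). Neutrophil genes rose with them, among them S100a8 by 2.94 ± 0.25 (adjusted p = 8.82e-07) and S100a9 by 3.18 ± 0.28 (adjusted p = 1.2e-06), which encode calprotectin, and the gelatinase gene Mmp9 by 3.77 ± 0.23 (adjusted p = 1.76e-08). Cxcr2 differed by 0.14 ± 0.10 (adjusted p = 0.543). The CXCR2 ligand list was shifted (camera adjusted p = 4.41e-07), with 3 of 3 members by either adjustment, and so was the mature neutrophil list (camera adjusted p = 4.02e-13), with 6 of 12 risen and 9 adjusted over the list alone. CC chemokines were shifted upward (camera adjusted p = 8.52e-06, 5 of 14 risen, 7 adjusted over the list alone), with Ccl2 up by 3.04 ± 0.35 (adjusted p = 2.91e-05) and Ccl7 by 2.35 ± 0.24 (adjusted p = 7.79e-06). Of 18 chemokine receptors 1 rose, Ccr2 by 1.17 ± 0.24 (adjusted p = 0.00521), which with the beta-actin covariate had an adjusted p of 0.0572 (range over 12 settings 0.000327 to 0.0572). Adjusted over the list alone, 2 receptors were higher and 3 lower, and the list was not shifted (camera adjusted p = 0.547). The count of 555 changed genes moved to 359 without day 0 replicate 4.

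Besides Mmp9, at day 7 Mmp3 rose by 3.72 ± 0.27 (13.2-fold, adjusted p = 1.42e-07), the collagenase gene Mmp13 by 3.33 ± 0.31 (adjusted p = 1.84e-06) and the inhibitor gene Timp1 by 2.53 ± 0.23 (adjusted p = 1.55e-06). Other probe sets moved less, with 0.27 for Timp1 and 2.06 for Mmp9. The matrix degradation list was shifted upward (camera adjusted p = 3.97e-10), with 6 of 13 risen and 7 adjusted over the list alone. C1qtnf3, which encodes a secreted C1q and TNF related protein, rose by 4.16 ± 0.42 (adjusted p = 7.08e-06). Falls were led by the cartilage intermediate layer gene Cilp2, which fell by 2.50 ± 0.24 (adjusted p = 2.84e-06). The lymphatic hyaluronan receptor gene Lyve1 (-2.47 ± 0.34, adjusted p = 0.000173), the tenascin gene Tnxb (-2.44 ± 0.49, adjusted p = 0.00428) and the actin severing gene Gsn (-2.42 ± 0.26, adjusted p = 1.67e-05) fell too. The circadian clock genes Dbp (-2.24 ± 0.30, adjusted p = 0.000149) and Nr1d1 (-2.15 ± 0.37, adjusted p = 0.0012) fell as well. Of 10 cartilage genes 1 rose and 1 fell by either adjustment, and the list was not shifted (camera adjusted p = 0.561). The rise was that of aggrecan, Acan (1.79 ± 0.28, adjusted p = 0.00074), and the fall that of chondroadherin, Chad (-1.04 ± 0.21, adjusted p = 0.0049). The Chad call was lost with the beta-actin covariate (adjusted p = 0.0706, range over 12 settings 4.75e-05 to 0.0706).

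Synovial fibroblast genes were shifted upward at day 7 (camera adjusted p = 0.00225, lost at adjusted p = 0.143 with an estimated correlation), with 3 of 13 risen and 5 adjusted over the list alone. Periostin, Postn, rose by 1.89 ± 0.38 (adjusted p = 0.00462) and podoplanin, Pdpn, of low signal, by 0.77 ± 0.11 (adjusted p = 0.000224). The adhesion molecule gene Vcam1 rose by 1.81 ± 0.30 (adjusted p = 0.00114) on the chosen probe set and by 0.75 on the mean of its probe sets (adjusted p = 0.0564, range over 12 settings 8.27e-06 to 0.0564). Adipocyte genes were shifted downward (camera adjusted p = 0.00148, lost at adjusted p = 0.1 with an estimated correlation), with 2 of 6 fallen and 4 adjusted over the list alone. The adipokine gene Retn fell by 1.34 ± 0.18 (adjusted p = 0.000149). Inflammatory cytokine genes were shifted upward (camera adjusted p = 0.0129, lost at adjusted p = 0.315 with an estimated correlation), with 4 of 14 higher and 1 lower by either adjustment. The interleukin 1 antagonist gene Il1rn rose by 2.48 ± 0.29 (adjusted p = 3.38e-05) and Il1b by 1.63 ± 0.26 (adjusted p = 0.000707). The RANKL gene Tnfsf11 rose by 1.56 ± 0.21 (adjusted p = 0.00015), near background (at most 5.19 at day 7). Csf1 fell by 0.58 ± 0.15 (adjusted p = 0.0201), a call lost without day 0 replicate 4 (adjusted p = 0.0667), day 7 replicate 3 (0.0607) or day 7 replicate 4 (0.0689). Proliferation genes were shifted upward (camera adjusted p = 7.73e-13), with 6 of 12 risen and 11 adjusted over the list alone, among them Top2a (2.04 ± 0.22, adjusted p = 1.39e-05) and Cdk1 (1.51 ± 0.20, adjusted p = 0.000125).

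At day 12 Saa3 and the lists of matrix degradation and CXCR2 ligand genes stood above their levels before serum, with 154 genes higher and 113 lower (3 arrays against 4). Saa3 rose by 5.69 ± 0.35 (adjusted p = 4.26e-08), C1qtnf3 by 4.60 ± 0.46 (adjusted p = 7.24e-06), Mmp13 by 4.45 ± 0.33 (adjusted p = 2.68e-07) and Mmp3 by 3.86 ± 0.29 (14.5-fold, adjusted p = 2.68e-07). All 3 CXCR2 ligands rose, Cxcl1 by 2.95 ± 0.47 (adjusted p = 0.00121), Cxcl2 by 2.46 ± 0.24 (adjusted p = 6.32e-06) and Cxcl5 by 2.83 ± 0.45 (adjusted p = 0.00118), while Cxcr2 differed by 0.13 (adjusted p = 0.679). The list was shifted upward (camera adjusted p = 8.15e-09), with 3 of 3 by either adjustment. Arg1, the arginase of alternatively activated macrophages and of liver, rose by 3.06 ± 0.60 (adjusted p = 0.00689), and by 3.11 without the arrays with liver transcripts (adjusted p = 0.00337). With the beta-actin covariate Arg1 had an adjusted p of 0.168, and its range over 12 settings was 3.3e-05 to 0.168. Lyve1 fell by 2.46 ± 0.37 (adjusted p = 0.000703) and Gsn by 2.17 ± 0.29 (adjusted p = 2e-04). The leukotriene C4 synthase gene Ltc4s fell by 1.84 ± 0.33 (adjusted p = 0.00297) on the chosen probe set, while its other probe set differed by 0.05. The count of 267 changed genes moved to 558 without day 0 replicate 2, to 152 without day 0 replicate 3, to 114 without day 12 replicate 2 and to 154 without day 12 replicate 3.

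Neutrophil genes were again shifted upward at day 12 (camera adjusted p = 1.29e-12), with 4 of 12 risen and 8 adjusted over the list alone, among them Mmp9 (2.80 ± 0.25, adjusted p = 2.16e-06, other probe set 1.15) and S100a8 (2.65 ± 0.27, adjusted p = 8.29e-06). CC chemokines were shifted (camera adjusted p = 5.51e-05, 3 of 14 risen, 6 adjusted over the list alone), with Ccl2 up by 2.86 ± 0.38 (adjusted p = 2e-04). Matrix degradation genes were shifted upward (camera adjusted p = 4.27e-10), with 4 of 13 risen and 5 adjusted over the list alone. Synovial fibroblast genes were shifted upward (camera adjusted p = 6.21e-07), with 3 of 13 risen and 6 adjusted over the list alone, among them Vcam1 (2.00 ± 0.33, adjusted p = 0.00144, lowest of 3 probe sets 0.43) and Postn (2.20 ± 0.41, adjusted p = 0.00476). Interferon response genes were shifted upward (camera adjusted p = 0.00176), with 2 of 10 risen by either adjustment. Of these Ifit1 rose by 0.94 ± 0.17 (adjusted p = 0.00332). Isg15 rose by 0.71 (adjusted p = 0.0274) but did not pass without day 0 replicate 3 (adjusted p = 0.0723), day 0 replicate 4 (0.0645), day 12 replicate 1 (0.0938) or day 12 replicate 3 (0.0837). Skeletal muscle genes were shifted downward (camera adjusted p = 0.0018, 0 of 13 by either adjustment, median -0.95), and this was lost (adjusted p = 0.399 with an estimated correlation). Acta1 differed by -1.57 (adjusted p = 0.134).

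At day 18 Saa3 and the lists of matrix degradation and mature neutrophil genes were above their levels before serum (3 arrays against 4), and the calls of several chemokines rested on single arrays. Saa3 rose by 5.54 ± 0.35 (adjusted p = 6.65e-08), Mmp13 by 4.85 ± 0.33 (adjusted p = 8.92e-08) and Mmp3 by 4.01 ± 0.29 (16.1-fold, adjusted p = 1.43e-07). The matrix degradation list was shifted upward (camera adjusted p = 2.41e-14), with 4 of 13 risen and 8 adjusted over the list alone. Cxcl2 rose by 2.34 ± 0.24 (adjusted p = 9.89e-06), Cxcl5 by 2.34 ± 0.45 (adjusted p = 0.0082) and Cxcl1 by 2.09 ± 0.47 (adjusted p = 0.0255), while Cxcr2 differed by 0.21 (adjusted p = 0.524). The ligand list was shifted (camera adjusted p = 3.52e-08), with 3 of 3 by either adjustment. The Cxcl5 call was lost without day 18 replicate 3 (adjusted p = 0.0795), and that of Cxcl1 without day 0 replicate 3 (0.0811), day 18 replicate 1 (0.114) or day 18 replicate 3 (0.173). Lyve1 fell by 2.56 ± 0.37 (adjusted p = 0.000447) and the peroxidase gene Gpx3 by 1.89 ± 0.31 (adjusted p = 0.00197). In all, 93 genes were higher and 73 lower. The count of 166 moved to 89 without day 0 replicate 3, 102 without day 0 replicate 4, 82 without day 18 replicate 1, 94 without day 18 replicate 2 and 56 without day 18 replicate 3.

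Neutrophil genes were shifted upward at day 18 (camera adjusted p = 1.93e-18), with 5 of 12 risen and 9 adjusted over the list alone, among them S100a9 (3.43 ± 0.30, adjusted p = 1.21e-06) and Mmp9 (3.02 ± 0.25, adjusted p = 9.34e-07, other probe set 1.01). Genes of neutrophil granules, which are made in precursors, were shifted too (camera adjusted p = 8.9e-07, 4 of 10 risen by either adjustment), though not by the other test (adjusted p = 0.0709 with an estimated correlation). The cathelicidin gene Camp rose by 1.53 ± 0.24 (adjusted p = 0.00141). The lactoferrin gene Ltf rose by 0.88 (adjusted p = 0.00692), a call lost without day 18 replicate 3 (adjusted p = 0.0597). CC chemokines were shifted upward (camera adjusted p = 0.000123), with 3 of 14 risen and 5 adjusted over the list alone, and Ccl2 rose by 1.93 ± 0.38 (adjusted p = 0.00841), but not without day 18 replicate 3 (adjusted p = 0.065). Adipocyte genes were shifted downward (camera adjusted p = 1.57e-07), with 2 of 6 fallen and 5 adjusted over the list alone, and Retn fell by 1.59 ± 0.19 (adjusted p = 9.76e-05). Inflammatory cytokine genes were shifted upward (camera adjusted p = 0.0115, lost at adjusted p = 0.269 with an estimated correlation), with 3 of 14 higher over all genes, and 4 higher and 1 lower adjusted over the list alone. Il1rn rose by 2.68 ± 0.31 (adjusted p = 5.45e-05) and Il1b by 2.02 ± 0.28 (adjusted p = 0.000318).

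Between day 7 and day 18 the ankle changed in few genes, and 5 were higher and 0 lower at day 18 (limma, 436 at an unadjusted p under 0.05, 3 arrays against 4). Cilp2 rose by 1.70 ± 0.26 (adjusted p = 0.0136), toward its level before serum (12.84 at day 0, 10.34 at day 7 and 12.04 at day 18). The granule genes Ltf (1.13 ± 0.17, adjusted p = 0.0136), Camp (1.503 ± 0.239, adjusted p = 0.019) and Ngp (1.74 ± 0.30, adjusted p = 0.0433) rose, as did Sfrp4, a secreted inhibitor of Wnt signalling (1.297 ± 0.232, adjusted p = 0.0456). The granule precursor list was shifted upward (camera adjusted p = 2.52e-08, 3 of 10 by either adjustment). The proliferation list was shifted downward (camera adjusted p = 2.52e-08, 0 of 12 over all genes, 2 adjusted over the list alone), and both calls were lost (each adjusted p = 0.169 with an estimated correlation). Top2a differed by -0.95 (adjusted p = 0.295), Cxcl1 by -0.81 (adjusted p = 0.999), Cxcl2 by 0.53 (adjusted p = 0.903), Cxcl5 by -0.44 and Cxcr2 by 0.06 (both adjusted p = 0.999). The count of 5 moved to 0 without day 7 replicate 2 or day 7 replicate 3, 1 without day 18 replicate 1 and 3 without day 18 replicate 2 or day 18 replicate 3. Sfrp4 lost its call in each of 7 fits, with adjusted p 0.0849 without day 7 replicate 1, 0.0841 without day 7 replicate 2, 0.174 without day 7 replicate 3, 0.137 without day 7 replicate 4, 0.57 without day 18 replicate 1, 0.152 without day 18 replicate 2 and 0.142 without day 18 replicate 3. Ngp lost it without day 7 replicate 1 (adjusted p = 0.0633), without day 7 replicate 2 (0.133), day 7 replicate 3 (0.139), day 18 replicate 1 (0.278) or day 18 replicate 3 (0.163). Without day 7 replicate 2 or day 7 replicate 3 the values were 0.0558 and 0.0514 for Cilp2 and Ltf and 0.0841 and 0.0514 for Camp. Cilp2 also lost its call without day 18 replicate 1 (adjusted p = 0.107) or day 18 replicate 2 (0.121). Camp lost it without day 18 replicate 1 (0.203) or day 18 replicate 3 (0.133).

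**Figure D2:**
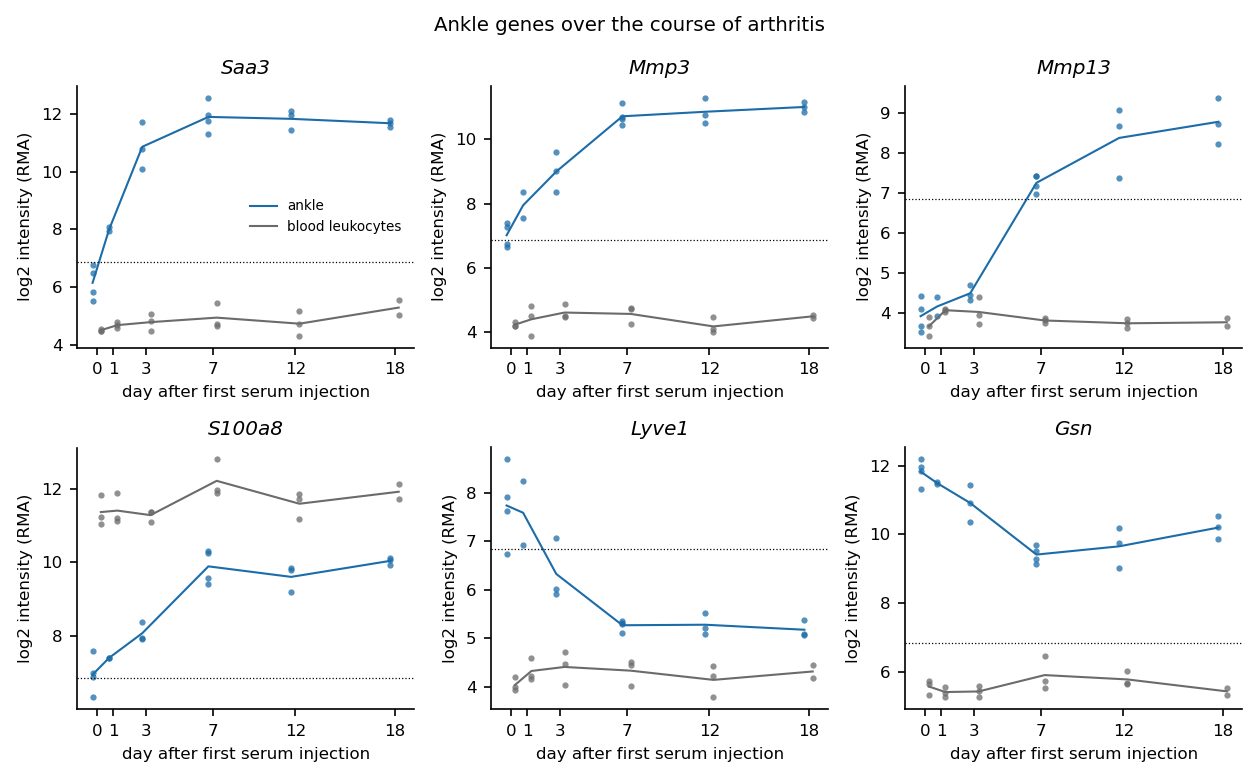
Log2 intensity (RMA, vertical axis) of Saa3, Mmp3, Mmp13, S100a8, Lyve1 and Gsn on each array by day after the first serum injection (horizontal axis) in ankle and blood, with lines through the group means. Mean Saa3 in ankle went from 6.14 at day 0 to 11.68 at day 18. Its means in blood lay between 4.50 and 5.29.

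In blood leukocytes no gene passed the test at any day, against day 0 (3 arrays per group, 2 at day 18). In limma 0 of 8252 genes passed, and 589, 1702, 169, 513 and 1694 genes had an unadjusted p under 0.05 at days 1, 3, 7, 12 and 18. Neutrophil genes were shifted upward at day 7 (camera adjusted p = 1.31e-05, 0 of 12 by either adjustment), a call lost by the other test (adjusted p = 0.661 with an estimated correlation). S100a8 differed by 0.85 ± 0.28 and S100a9 by 0.89 ± 0.30 (both adjusted p = 0.999). B cell genes were shifted downward at day 12 (camera adjusted p = 0.000487), with 0 of 10 over all genes and 1 adjusted over the list alone. The antigen receptor gene Cd79b differed by -0.60 ± 0.18 and the transcription factor gene Pax5 by -0.86 ± 0.33 (both adjusted p = 0.664). Cxcl1 differed by 0.05, 0.18, 0.35, 0.20 and 1.67 at these days in turn, the last with an adjusted p of 0.22. Without day 18 replicate 1 it passed at day 18 (adjusted p = 0.0138), where 2 genes then did. Cxcl2 differed by -0.51, -0.91, 0.57, -0.15 and 0.89, Cxcl5 by -0.02, -0.01, 0.02, -0.07 and -0.02, and Cxcr2 by -0.19, -0.19, 0.08, 0.07 and -0.01, none past the test. The ligand list did not pass at day 1 (camera adjusted p = 0.696, 0 of 3), day 3 (0.551, 0 of 3) or day 18 (0.286, 0 of 3 over all genes and 1 adjusted over the list alone).

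The blood arrays differed in the spread of their signal. The interquartile range of log2 values was 2.71 to 2.80 in the day 0 arrays. It was 2.73 in day 3 replicate 1 (others of day 3 2.51 and 2.52) and 2.80 in day 12 replicate 1 (others of day 12 2.57 and 2.63). Without day 3 replicate 1, 1100 genes passed at day 3 in place of 0. Without both these arrays, chosen after seeing the data, 2559 passed at day 3, 308 at day 12 and 156 at day 18. Both had the spread of day 0, so that day and spread then coincide. At day 7 replicate 1 stood at 2.73 against 2.65 and 2.69.

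The interaction of tissue and day asked whether the ankle response differed from that of blood, and at day 7 it did for 188 genes, 88 of them higher in the ankle response (4 arrays per group in ankle, 3 in blood). The ankle response exceeded that of blood by 5.32 ± 0.44 for Saa3 (adjusted p = 4.99e-09), and for C1qtnf3 by 4.21 ± 0.51 (adjusted p = 6.45e-06). It did so for Mmp3 by 3.38 ± 0.36 (adjusted p = 1.19e-06), Mmp9 by 3.27 ± 0.42 (adjusted p = 1.45e-05, other probe set 1.4) and Mmp13 by 3.18 ± 0.38 (adjusted p = 6.45e-06). Lyve1 (-2.76 ± 0.44, adjusted p = 0.000239), Gsn (-2.75 ± 0.36, adjusted p = 1.45e-05) and Cilp2 (-2.56 ± 0.32, adjusted p = 6.94e-06) had a lower response in ankle than in blood, where they differed by 0.295, 0.332 and 0.057 (each adjusted p = 0.999). For Cxcl5 the difference was 2.75 ± 0.51 (adjusted p = 0.00155), for Cxcl2 1.24 ± 0.58 (adjusted p = 0.439) and for Cxcr2 0.06 (adjusted p = 0.994). For Cxcl1 it was 2.55 ± 0.62 (adjusted p = 0.0216), which was lost without ankle day 0 replicate 3 (adjusted p = 0.0556), blood day 0 replicate 2 (0.0713), blood day 7 replicate 2 (0.0722) or blood day 7 replicate 3 (0.076). Cxcl2 passed without blood day 7 replicate 1 (adjusted p = 0.0491). The count moved to 111 without blood day 0 replicate 1 and to 124 without blood day 7 replicate 3. At days 1, 3, 12 and 18 the interaction was past the threshold for 0, 11, 158 and 111 genes.

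By group, the day 7 difference was upward in ankle for the CXCR2 ligands (camera adjusted p = 8.5e-06, 2 of 3 over all genes and 3 adjusted over the list alone). It was upward for CC chemokines too (camera adjusted p = 5.2e-05, 2 of 14 by either adjustment), with Ccl7 at 2.44 ± 0.32 (adjusted p = 2.08e-05) and Ccl2 at 2.62 ± 0.46 (adjusted p = 0.000929). Matrix degradation genes differed as a group (camera adjusted p = 3.15e-09, 4 of 13 by either adjustment), with Timp1 at 2.38 ± 0.32 (adjusted p = 2.56e-05) and its other probe set at 0.19. Proliferation genes differed too (camera adjusted p = 9.28e-15), with 5 of 12 over all genes and 7 adjusted over the list alone, and Top2a stood at 2.41 ± 0.29 (adjusted p = 6.45e-06). Mature neutrophil genes were shifted (camera adjusted p = 3.05e-06, 4 of 12 by either adjustment), but not by the other test (adjusted p = 0.113 with an estimated correlation), with S100a8 at 2.09 ± 0.39 (adjusted p = 0.00185).

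The fluid comparisons ask how cells in the joint space changed after day 3, the earliest fluid analysed here. At day 7 the synovial fibroblast list stood higher than at day 3, and the CC chemokine list lower (4 arrays against 3). Lumican, Lum, rose by 3.37 ± 0.36 (adjusted p = 6.27e-05), and Mmp3 by 3.32 ± 0.34 (adjusted p = 4.53e-05), from day 3 means of 6.41 and 5.60 that lay within the range of the negative controls, so that both rises are at best lower bounds. The collagen genes rose with them, Col5a2 by 3.03 ± 0.20 (adjusted p = 1.35e-06) and Col3a1 by 2.36 ± 0.29 (adjusted p = 0.000203), and lysyl oxidase, Lox, by 2.85 ± 0.28 (adjusted p = 3.72e-05). Il4 fell by 2.34 ± 0.30 (adjusted p = 0.000311), Ccl7 by 2.08 ± 0.32 (adjusted p = 0.00136), Ccl2 by 1.87 ± 0.27 (adjusted p = 0.00084) and the chitinase-like gene Chil3 by 1.96 ± 0.29 (adjusted p = 0.00102). Il4, in the lowest 0.333 of mean signal, had 5 probe sets between -2.34 and -0.20, and the other probe set of Lox differed by 0.64. Cxcl5 rose by 2.41 ± 0.42 (adjusted p = 0.00338), Cxcl2 differed by -0.74 (adjusted p = 0.537) and Cxcr2 by 0.27 (adjusted p = 0.776). Cxcl1 rose by 1.52 ± 0.38 (adjusted p = 0.0417), a call lost without day 3 replicate 1 (adjusted p = 0.137), day 3 replicate 2 (0.176), day 3 replicate 3 (0.0608), day 7 replicate 2 (0.107) or day 7 replicate 3 (0.136). In all, 179 genes were higher and 32 lower, and 112 passed with only the arrays prepared during dissection, chosen after seeing the data. The beta-actin ratio was 1.59 to 2.40 in the day 3 fluid arrays and 1.88 to 3.61 later. With it as a covariate 144, 199 and 164 genes passed at days 7, 12 and 18.

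Synovial fibroblast genes were shifted upward in fluid at day 7 (camera adjusted p = 4.17e-17), with 8 of 13 risen by either adjustment, among them Postn (2.19 ± 0.23, adjusted p = 6.27e-05) and the fibroblast activation protein gene Fap (2.05 ± 0.26, adjusted p = 0.000224), whose means at both days lay within the range of the negative controls (at most 6.11 for Postn and 6.04 for Fap). Matrix degradation genes were shifted upward (camera adjusted p = 1.89e-08), with 5 of 13 risen and 8 adjusted over the list alone, among them Mmp9 (1.54 ± 0.30, adjusted p = 0.00796). The call of Mmp2 (0.87 ± 0.14, adjusted p = 0.00217) rested on its chosen probe set, since the other differed by -0.07. CC chemokines were shifted downward (camera adjusted p = 7.99e-08), with 4 of 14 fallen and 8 adjusted over the list alone. One of these falls, that of Ccl4 (-1.35, adjusted p = 0.0405), was lost without day 3 replicate 1 (adjusted p = 0.159), day 3 replicate 3 (0.145), day 7 replicate 3 (0.0744) or day 7 replicate 4 (0.113), and with the replicate numbers as a block (0.12, range over 13 settings 0.000578 to 0.261). The CXCR2 ligand list was shifted upward (camera adjusted p = 0.0344, 2 of 3 by either adjustment), which was lost (adjusted p = 0.377 with an estimated correlation). Interferon response genes were shifted upward (camera adjusted p = 0.00148, 1 of 10 risen, 4 adjusted over the list alone), also lost (adjusted p = 0.377 with an estimated correlation). Its member Ifit2 differed by 1.13 (adjusted p = 0.119), and passed without day 7 replicate 4 (adjusted p = 0.022) or with the block (0.0134). Proliferation genes were shifted upward (camera adjusted p = 1.55e-05), with 3 of 12 risen and 5 adjusted over the list alone, among them Cdk1 (1.00 ± 0.19, adjusted p = 0.00656).

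At day 12 Lum was up by 3.97 ± 0.39 (adjusted p = 2.25e-05), Postn by 3.34 ± 0.25 (adjusted p = 2.71e-06), Col5a2 by 3.45 ± 0.21 (adjusted p = 5.56e-07) and Mmp13 by 3.18 ± 0.53 (adjusted p = 0.00242) over day 3 (3 arrays each). Chil3 fell by 2.11 ± 0.31 (adjusted p = 0.00091). The synovial fibroblast list was shifted upward (camera adjusted p = 1.25e-15), with 9 of 13 risen by either adjustment. Matrix degradation genes were shifted (camera adjusted p = 3.64e-05, 5 of 13 risen, 7 adjusted over the list alone), a call lost by the other test (adjusted p = 0.0966 with an estimated correlation). Cxcl5 rose by 2.85 ± 0.45 (adjusted p = 0.00153), Cxcl2 differed by 0.28 (adjusted p = 0.794) and Cxcr2 by 0.42 (adjusted p = 0.445). Cxcl1 rose by 1.74 ± 0.40 (adjusted p = 0.0265), a call lost without day 3 replicate 1 (adjusted p = 0.0973), day 3 replicate 2 (0.116), day 12 replicate 1 (0.143) or day 12 replicate 3 (0.0729). The ligand list was shifted (camera adjusted p = 0.00138, 2 of 3 by either adjustment). The CC chemokine list was shifted downward (camera adjusted p = 0.0183, 2 of 14 fallen, 3 adjusted over the list alone), and both calls were lost (adjusted p = 0.243 and 0.189 with an estimated correlation). Interferon response genes were shifted upward (camera adjusted p = 0.00269, 1 of 10 risen, 2 adjusted over the list alone, and adjusted p = 0.466 with an estimated correlation), with Ifit1 up by 1.86 ± 0.28 (adjusted p = 0.00111). In all, 200 genes were higher and 23 lower, and the count of 223 moved to 141 without day 12 replicate 3.

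At day 18 Lum was 3.85 ± 0.39 above day 3 (adjusted p = 2.87e-05), Fap 2.84 ± 0.27 (adjusted p = 2.45e-05), Mmp3 3.54 ± 0.36 (adjusted p = 3.16e-05) and the growth arrest gene Gas1 3.14 ± 0.29 (adjusted p = 1.79e-05), with 3 arrays each. Chil3 fell by 2.39 ± 0.31 (adjusted p = 0.000281), Ccl7 by 2.21 ± 0.34 (adjusted p = 0.00133), Ccl2 by 1.51 ± 0.29 (adjusted p = 0.00678) and the sphingosine kinase gene Sphk1 by 1.56 ± 0.22 (adjusted p = 0.000646). As a list, synovial fibroblast genes were shifted upward (camera adjusted p = 2.04e-13), with 8 of 13 risen and 9 adjusted over the list alone. The list of CC chemokines was shifted downward (camera adjusted p = 0.000264), with 4 of 14 fallen and 6 adjusted over the list alone. Matrix degradation genes were shifted upward (camera adjusted p = 0.000761, 3 of 13 risen, 5 adjusted over the list alone), a call lost by the other test (adjusted p = 0.154 with an estimated correlation). Cxcl1 differed by 0.70 (adjusted p = 0.46), Cxcl2 by 0.11 (adjusted p = 0.944) and Cxcr2 by 0.22 (adjusted p = 0.71), and the ligand list did not pass (camera adjusted p = 0.109, 1 of 3 by either adjustment). Cxcl5 rose by 1.74 ± 0.45 (adjusted p = 0.0486), a call lost without day 3 replicate 1 (adjusted p = 0.11), day 3 replicate 2 (0.142), day 3 replicate 3 (0.0978), day 18 replicate 1 (0.13), day 18 replicate 2 (0.0603) or day 18 replicate 3 (0.202). In all, 188 genes were higher and 75 lower. The count of 263 moved to 164 without day 3 replicate 2, 136 without day 18 replicate 1 and 169 without day 18 replicate 2.

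**Figure D3:**
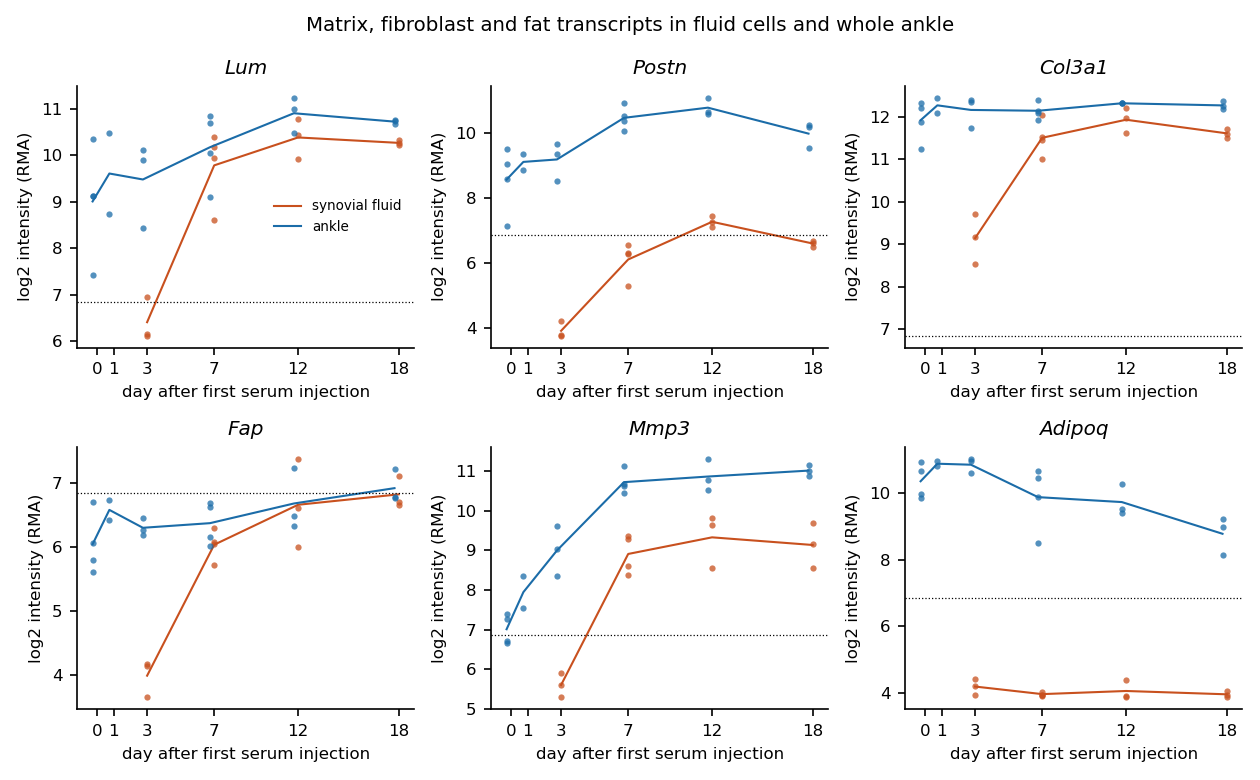
Log2 intensity (RMA, vertical axis) of Lum, Postn, Col3a1, Fap, Mmp3 and Adipoq on each array by day after the first serum injection (horizontal axis) in fluid cells and ankle, with lines through the group means. Mean Lum in fluid went from 6.41 at day 3 to 9.78 at day 7 and 10.38 at day 12.

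Cells of the fluid were compared with blood leukocytes of the same days to ask how cells in the joint differed from those in circulation. Most monocyte and macrophage and most synovial fibroblast genes were higher in fluid, and most T, B and NK cell genes lower (13 fluid arrays and the blood arrays of days 3 to 18). The complement gene C1qb was higher by 6.46 ± 0.11 (adjusted p = 1.84e-25), Arg1 by 7.08 ± 0.18 (adjusted p = 5.52e-22), decorin, Dcn, by 7.46 ± 0.17 (adjusted p = 4.32e-23) and Ccl2 by 5.30 ± 0.13 (adjusted p = 4.7e-22). The other probe set of C1qb differed by 0.32 and that of Ms4a1 by -2.94. Of the B cell genes Cd79b was lower by 4.77 ± 0.10 (adjusted p = 1.06e-23) and Ms4a1 had a difference of -4.82 ± 0.12 (adjusted p = 5.51e-22). The T cell gene Cd8b1 had one of -5.04 ± 0.12 (adjusted p = 2.19e-22). All 3 CXCR2 ligands were higher in fluid, Cxcl1 by 3.37 ± 0.21 (adjusted p = 1.33e-13), Cxcl5 by 2.13 ± 0.18 (adjusted p = 6.92e-11) and Cxcl2 by 1.497 ± 0.258 (adjusted p = 1.97e-05, in 12 of 13 fluid arrays). Cxcr2 was higher by 0.49 ± 0.10 (adjusted p = 0.000186), at levels within the range of the negative controls in both. By day, Cxcl1 was higher in fluid by 2.80, 4.15, 4.51 and 2.00 at days 3, 7, 12 and 18, and Cxcl5 by 0.37 (adjusted p = 0.44), 2.75, 3.28 and 2.12. Cxcl2 differed by 2.59, 0.37 (adjusted p = 0.61), 2.11 and 0.91 (adjusted p = 0.298). In all, 2050 genes were higher and 2804 lower in fluid, 58.8% of those tested.

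Monocyte and macrophage genes were shifted upward in fluid over blood (camera adjusted p = 3.93e-11), with 12 of 13 higher and 1 lower by either adjustment. C1qa was higher by 4.12 ± 0.11 (adjusted p = 1.53e-21) and Cd14, the endotoxin co-receptor, by 3.56 ± 0.13 (adjusted p = 6.27e-19), while Marco was lower by 0.31 ± 0.08 (adjusted p = 0.00122). T cell genes were shifted downward (camera adjusted p = 2.21e-09), with 12 of 13 lower and 13 adjusted over the list alone, among them Cd28 (-2.78 ± 0.11, adjusted p = 1.09e-17). Probe sets of Cd3d did not go together, with -4.37 ± 0.13 for the chosen one (adjusted p = 1.62e-20) and 0.04 for the other. All 10 B cell genes were lower (camera adjusted p = 1.75e-10, by either adjustment), and Ighm, at -3.85 ± 0.11 (adjusted p = 1.53e-20), had 16 probe sets between -5.22 and 0.15. All 7 NK cell genes were lower (camera adjusted p = 3.2e-06, by either adjustment), among them granzyme A, Gzma (-3.62 ± 0.12, adjusted p = 1.89e-19). Synovial fibroblast genes were shifted upward (camera adjusted p = 4.55e-08), with 10 of 13 higher and 1 lower by either adjustment. Col3a1 was higher by 4.16 ± 0.12 (adjusted p = 6.96e-21), and Thy1, which T cells also express in mice, was lower by 2.41 ± 0.14 (adjusted p = 3.15e-14).

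Mature neutrophil genes were mostly higher in fluid than in blood (10 of 12 higher and 1 lower by either adjustment, camera adjusted p = 0.000372), a shift lost by the other test (adjusted p = 0.206 with an estimated correlation). Clec4d was higher by 2.89 ± 0.21 (adjusted p = 3.98e-12) and the decoy receptor gene Il1r2 by 1.98 ± 0.18 (adjusted p = 2.99e-10). Ly6g was lower by 0.27 ± 0.09 (adjusted p = 0.0131), and with array weights had an adjusted p of 0.0542 (range over 14 settings 0.00676 to 0.0542). Of 10 granule precursor genes 1 was higher and 5 lower by either adjustment, and the list was not shifted (camera adjusted p = 0.446). The myeloperoxidase gene Mpo was lower by 0.50 ± 0.08 (adjusted p = 9.16e-06), and on its other probe set by 0.20. Chil3 was higher by 0.85 ± 0.18 as a mean (adjusted p = 0.000256), with 2.61, 0.99, 0.43 (adjusted p = 0.359) and -0.64 (adjusted p = 0.289) at days 3, 7, 12 and 18. The CXCR2 ligand list was shifted upward (camera adjusted p = 0.00505, 3 of 3 by either adjustment), as were CC chemokines (camera adjusted p = 0.00632, 8 of 14 higher and 2 lower by either adjustment), and both were lost (adjusted p = 0.113 and 0.0602 with an estimated correlation). Ccl7 was higher by 3.51 ± 0.14 (adjusted p = 1.66e-17) and Ccl5, a product of T and NK cells, was lower by 4.66 ± 0.16 (adjusted p = 6.28e-19). Chemokine receptors went both ways, with 6 of 18 higher and 9 lower by either adjustment (camera adjusted p = 0.735, downward, where the median was -0.18 and the mean 0.28). The scavenging receptor gene Ackr3 was higher by 4.88 ± 0.17 (adjusted p = 4.67e-19), and Ccr7, which guides lymphocytes to lymph nodes, was lower by 2.23 ± 0.15 (adjusted p = 5.88e-13).

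Fluid cells were also compared with the whole ankle of the same days, 2 kinds of sample that differ in RNA preparation by the labels (13 arrays each). Most mature neutrophil (11 of 12) and most monocyte and macrophage genes (11 of 13) were higher in fluid. Most skeletal muscle (10 of 13) and adipocyte genes (5 of 6) were lower, with the shift of the muscle list lost by the other test (adjusted p = 0.0721). The itaconate producing enzyme gene Acod1 was higher by 4.65 ± 0.19 (adjusted p = 3.46e-17), and Il1rn by 4.22 ± 0.19 (adjusted p = 2.65e-16). Cxcl2 was higher by 4.02 ± 0.17 (adjusted p = 4.75e-17), Ccl3 by 3.74 ± 0.10 (adjusted p = 2.8e-21) and Il1b by 3.66 ± 0.20 (adjusted p = 7.63e-15). The other probe set of Acod1 differed by 1.07. Skeletal actin, Acta1, was lower by 6.78 ± 0.23 (adjusted p = 2.9e-19) and adiponectin, Adipoq, was lower by 5.78 ± 0.18 (adjusted p = 6.17e-20). Cxcl1 (0.04 ± 0.24, adjusted p = 0.924) and Cxcl5 (0.22 ± 0.25, adjusted p = 0.511) were not shown to differ between fluid and ankle, while Cxcr2 was higher in fluid by 1.01 ± 0.08 (adjusted p = 5.81e-11), at levels near background. The ligand list did not pass (camera adjusted p = 0.0821, 1 of 3 by either adjustment). By day, Cxcl2 was higher in fluid by 5.07, 3.45, 3.82 and 3.76 at days 3, 7, 12 and 18 (adjusted p = 1.23e-11, 1.89e-09, 5.33e-09 and 1.13e-08), at best lower bounds, since Cxcl2 in ankle lay within the range of the negative controls. In all, 1546 genes were higher in fluid and 1601 lower. The beta-actin ratio averaged 2.49 in fluid and 3.41 in ankle, and with it as a covariate 1435 genes passed in place of 3147.

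Mature neutrophil genes were shifted upward in fluid over ankle (camera adjusted p = 1.02e-11), with 11 of 12 higher and 1 lower by either adjustment. S100a8 was higher by 2.83 ± 0.13 (7.11-fold, adjusted p = 1.79e-16) and the formyl peptide receptor gene Fpr2 by 3.36 ± 0.17 (adjusted p = 1.83e-15), while Hp was lower by 0.60 ± 0.12 as a mean (adjusted p = 0.000122, in 9 of 13 fluid arrays). By day, Hp differed by -1.68, -0.69, -0.16 (adjusted p = 0.766) and 0.13 (adjusted p = 0.905). Monocyte and macrophage genes were shifted upward (camera adjusted p = 1.28e-10, 11 of 13 by either adjustment), with Cd14 higher by 2.94 ± 0.13 (adjusted p = 1.72e-16). CC chemokines were shifted upward (camera adjusted p = 0.000626), with 8 of 14 higher and 2 lower over all genes, and 9 and 2 adjusted over the list alone. Ccl4 was higher by 2.52 ± 0.15 (adjusted p = 5.43e-14). Ccl11, the eosinophil attractant eotaxin, was lower by 0.40 ± 0.08 (adjusted p = 0.000183). Ccl8 was lower by 1.204 ± 0.211 (adjusted p = 3.09e-05) but had an adjusted p of 0.158 with the beta-actin covariate (range over 14 settings 4.57e-07 to 0.158). Chemokine receptors were shifted upward (camera adjusted p = 0.0138, 8 of 18 higher and 3 lower by either adjustment), a call lost by the other test (adjusted p = 0.125 with an estimated correlation). Cxcr4 was higher by 2.61 ± 0.15 (adjusted p = 3.8e-14) and Ackr1, a venular receptor, was lower (-0.60 ± 0.07, adjusted p = 3.61e-08). Inflammatory cytokine genes were shifted upward (camera adjusted p = 0.00257, 6 of 14 by either adjustment), and this was lost too (adjusted p = 0.115 with an estimated correlation). Interferon response genes were shifted upward (camera adjusted p = 5.05e-06, 8 of 10 by either adjustment), with Rsad2 higher by 2.43 ± 0.18 (adjusted p = 5.34e-12), and this call was lost as well (adjusted p = 0.0775 with an estimated correlation).

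Between fluid and ankle the cartilage and epidermis lists were not shifted (camera adjusted p = 0.139 and 0.405, 4 and 2 of 10 genes lower). Of 13 skeletal muscle genes 10 were lower by either adjustment (camera adjusted p = 5.51e-09, and adjusted p = 0.0721 with an estimated correlation, so that the call was lost), among them Tnnc2 (-4.77 ± 0.23, adjusted p = 1.16e-15), whose other probe set differed by -0.02. Endothelial genes were shifted downward (camera adjusted p = 3.31e-07, 7 of 8 by either adjustment), among them the cadherin gene Cdh5 (-3.03 ± 0.16, adjusted p = 7.14e-15). Adipocyte genes were shifted downward (camera adjusted p = 1.51e-05, 5 of 6 by either adjustment), among them Fabp4 (-1.67 ± 0.13, adjusted p = 1.28e-11). Synovial fibroblast genes were shifted downward (camera adjusted p = 1.45e-05, 12 of 13 lower and 1 higher by either adjustment), with Postn lower by 4.12 ± 0.19 (adjusted p = 2.78e-16) and Col3a1 lower by 1.17 ± 0.14 (adjusted p = 3.79e-08). For Col3a1 this mean rested largely on day 3 (-3.01, adjusted p = 2.95e-09), with -0.64 (adjusted p = 0.0716), -0.39 (0.45) and -0.66 (0.16) at days 7, 12 and 18. Lum (-3.07, adjusted p = 0.000126), Fap (-2.31, 4.87e-07), Dcn (-2.77, 3.3e-07) and Pdgfra (-2.23, 2.93e-05) likewise passed at day 3 and at no later day, while Postn passed at every day. The exception was Pdpn, higher by 0.28 (adjusted p = 0.0493), with an adjusted p of 0.992 under the beta-actin covariate (range over 13 settings 0.00232 to 0.992). Its call was lost without replicate 1, 2 or 3 of ankle day 3 (adjusted p = 0.0559, 0.0631 and 0.0755), 1, 3 or 4 of ankle day 7 (0.0522, 0.0631 and 0.0707). So it was without replicate 1, 2 or 3 of ankle day 12 (0.0614, 0.0635 and 0.0662) and 1, 2 or 3 of ankle day 18 (0.0593, 0.0845 and 0.053). The same held for replicate 3 of fluid day 3 (0.118) and 2 or 3 of fluid day 7 (0.0707 and 0.0839). It also held for replicate 1 or 3 of fluid day 12 (0.105 and 0.0532) and 2 or 3 of fluid day 18 (0.0709 and 0.0899).

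**Figure D4:**
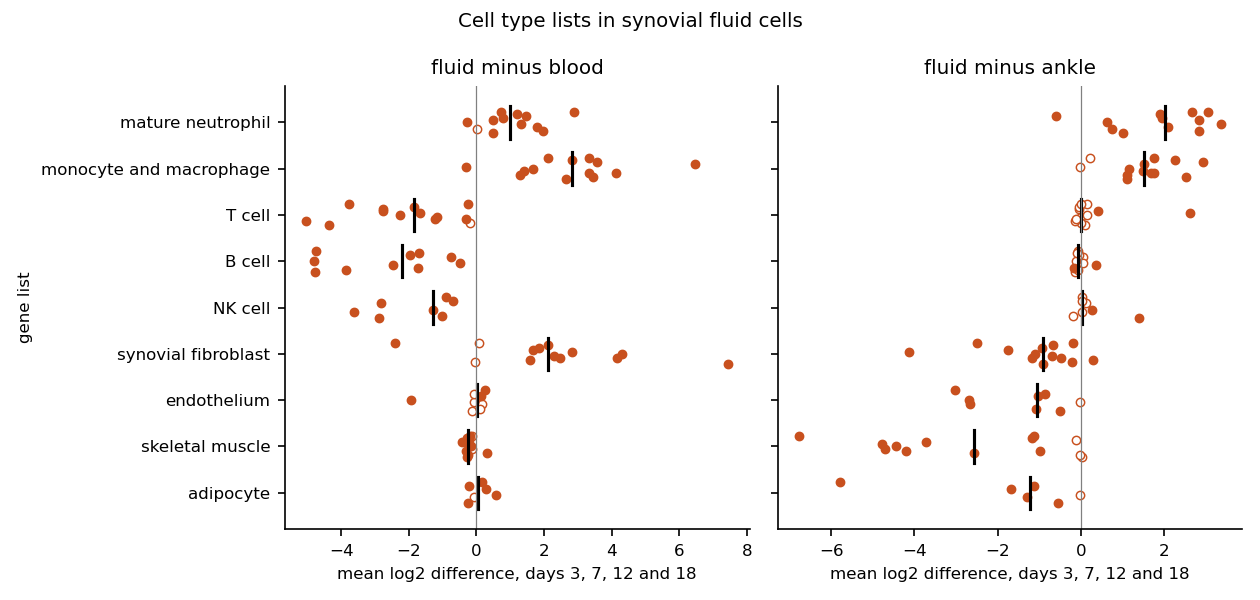
Log2 difference of each gene of 9 lists (vertical axis) between fluid and blood and between fluid and ankle, as the mean over days 3 to 18, with filled points for genes past the threshold and a bar at the median of each list. The B cell list lies at a median of -2.22 in fluid minus blood, and the monocyte and macrophage list at 2.83.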

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

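The interaction of tissue and day and the search for single arrays far from their group were planned before the data were examined, while the tests of liver transcripts, of the first component of the blood arrays and of stromal genes in fluid were chosen only after the result was seen. The ankle response to serum differed from the blood response in 188 genes at day 7, by a test of the difference itself. As many genes came from 5 of 100 splits (highest other 263), but splits can keep the ankle days apart and cannot judge chance. The response was larger in ankle for Saa3 (5.32), C1qtnf3 (4.21), the proteases Mmp3 (3.38), Mmp9 (3.27) and Mmp13 (3.18), Arg1 (2.93) and Timp1 (2.38). It was larger too for the chemokines Cxcl5 (2.75), Ccl2 (2.62), Cxcl1 (2.54) and Ccl7 (2.44), the myeloid genes Clec4d (2.92), S100a9 (2.29) and S100a8 (2.09), and the proliferation genes Top2a (2.41), Cdk1 (1.72), Birc5 (0.91) and Mcm2 (0.68). It was lower in ankle for Lyve1 (-2.76), Gsn (-2.75), Tnxb (-2.57), Cilp2 (-2.56), Itih5 (-2.42) and Dbp (-2.25). The other probe set stood at 0.11 for Itih5, 0.19 for Timp1 and 1.4 for Mmp9. The call of Tnxb was lost without blood day 7 replicate 3 (adjusted p = 0.051), that of Mcm2 without blood day 0 replicate 1 (0.0838) or blood day 7 replicate 2 (0.0878), and that of Cxcl1 as given above.

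Single arrays lay far from the others of their group in 21 of 555 pairs of a named gene and a group of 4 arrays, 3.8% where chance gives about 1 in 20. In ankle day 0 replicate 1, log2 intensity was 6.49 for Arg1 (nearest other array 4.26), 8.70 for Actc1 (10.77), 9.21 for C1qa (8.63), 10.05 for Ctsb (10.46) and 3.75 for Cd3d (3.43). In ankle day 0 replicate 2, Gja1 stood at 10.12 (9.07), Ccl9 at 8.20 (7.32) and Ackr1 at 7.83 (7.50), and in replicate 4 Marco stood at 4.37 (4.49). At ankle day 7, Calcr at 3.65 (3.1) and Plk1 at 7.99 (8.51) in replicate 1, Tnfsf11 at 4.81 (5.14) in replicate 2 and Col1a2 at 11.28 (12.39) in replicate 3 lay apart. In fluid day 7 replicate 4, Usp18 stood at 7.00 (8.33), Cilp2 at 8.90 (8.11), Pvalb at 10.29 (9.59) and Gp9 at 8.16 (7.73). Fluid day 7 replicate 2 had Fcgr1 at 9.63 (8.37), Il6 at 4.13 (3.48) and S100a8 at 12.56 (12.02), and replicate 1 had Thy1 at 7.36 (6.31).

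Liver transcripts stood out in replicate 1 of ankle days 0, 1, 7 and 12. The median of 14 liver genes exceeded the same-day replicates by 1.83, 0.85, 1.53 and 3.44, and 14, 14, 12 and 14 of them lay above every such replicate, with Alb at most 5.24 in fluid and blood. The excess of 1.83 on the day 0 array, before serum, argues against a response to serum. Genes near background differed by a median of 0.047 (0.136, 0.168, -0.043 and -0.197 in turn, 3994 genes). RMA levels the arrays, so that a higher background stays open. RNA from liver may be the source, since 12 of the 14 genes lay above every same-day replicate in all 4 arrays and 0 belong to another list. No sort or gate would remove such RNA from whole tissue, and how it entered the samples was not tested.

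The first component of the 17 blood arrays held 46.1% of the variance and followed the spread of signal (interquartile range, Pearson r = -0.965, Spearman rho = -0.975, both permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 3e-05 over 3 relations, r = -0.955 without the 2 arrays farthest out). A narrower spread on some arrays may underlie it, as 97.4% of 39 genes of muscle, epidermis, cartilage and bone had a positive loading. RNA quality stays open as well, with r = 0.584 and rho = 0.659 for the 3' to 5' beta-actin ratio (permutation p = 0.0122 and 0.00463, adjusted p = 0.0182 and 0.00694) and r = 0.70 without the 2 arrays farthest out. For the median of the negative controls r was 0.307 and rho 0.279 (permutation p = 0.238 and 0.277, adjusted p = 0.238 and 0.277, r = 0.198 without the 2 farthest). Day after serum and array quality cannot be told apart here (permutation p = 0.345 by day), since all day 0 arrays lie on 1 side (-20, -14.1 and -6.9).

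Stromal genes such as Lum and Postn rose in fluid after day 3, and carried-over tissue was weighed as a technical explanation. Explaining the rise needed 56.1% of ankle RNA at day 7, 65.6% at day 12 and 59.6% at day 18, yet muscle and adipocyte transcripts lay at -3.78, -3.1 and -3.55 of the level this predicts (log2, -4.05 to -3.62 over the day 7 arrays), which argues against whole ankle tissue as the whole cause. Endothelial transcripts lay at -1.63, -1.85 and -1.70 (-1.78 to -1.43 at day 7), against tissue as rich in vessels as ankle as the sole cause. Without the 4 arrays of other preparations the fibroblast list rose by a median of 1.66 in place of 1.79 at day 7, 1.78 in place of 1.99 at day 12 and 1.59 in place of 1.69 at day 18, with 6, 7 and 7 of 13 genes past the threshold, against preparation as the whole cause. Cells shed from the synovial lining, or fibroblast-like cells in the fluid, may carry these transcripts, a hypothesis not tested directly.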

How the results depend on the processing

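The beta-actin covariate and the leaving out of ankle arrays with liver transcripts, of blood arrays apart or of all 4 fluid arrays of other preparations were chosen only after the data were seen, and the other alternatives before. Of 11661 values of 461 named gene results under all alternatives but the last, 11112 stayed on their side of the threshold, 64 of them uncalled values with the other sign, 424 lost and 125 gained a call, and 0 called values reversed. Among the 5776 values that left out 1 array, 231 lost and 22 gained a call. By setting, calls lost and gained were 9 and 8 with quantile normalization anew, 8 and 2 with centred arrays, 31 and 1 with the floor, 9 and 4 with the mean of probe sets, 4 and 44 with array weights, 1 and 0 with robust eBayes, 5 and 23 with all arrays together, 53 and 0 at 2-fold, 5 and 13 with the block and 44 and 3 with the beta-actin covariate. They were 0 and 3 of 373 without the genes of lowest signal, 10 and 1 of 270 without the arrays with liver transcripts, 7 and 1 of 279 without arrays of another preparation, 7 and 0 of 223 without washed-out fluid, and 0 and 0 of 130 without the 2 blood arrays apart. Of 78 list calls, 32 were lost with an estimated correlation. The call of erythroid genes at ankle day 12 was lost with the mean of probe sets and with the block, the 1 list call each of these lost.

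Counts of changed genes that moved by more than 1.5 times are given by setting, and the cause was not tested unless the setting itself tests fewer changes. Array weights gave 525 at ankle day 3, 1273 at day 7, 2587 at day 12, 1542 at day 18 and 103 for day 18 against day 7, 3948 at blood day 3, 2237 at day 12 and 2335 at day 18, 485 at fluid day 7, 1638 at day 12 and 2753 at day 18, and 620 for the interaction. All 49 arrays in 1 fit gave 2 at ankle day 1, 68 at day 3, 458 at day 12, 295 at day 18, 30 for day 18 against day 7 and 506 at fluid day 18. The replicate block gave 917 at ankle day 7, 500 at day 12, 412 at day 18, 14 for day 18 against day 7 and 408 at fluid day 18. The beta-actin covariate gave 6 at ankle day 3, 249 at day 7, 95 at day 12, 104 at day 18, 164 at fluid day 18 and 1435 for fluid against ankle. A minimum of 2-fold, which asks for more by construction, gave 197 at ankle day 7, 139 at day 12, 99 at day 18, 133 at fluid day 7, 900 against blood and 622 against ankle. Quantile normalization anew gave 30 at ankle day 3 and 3 for day 18 against day 7, where the floor gave 0. Without the arrays with liver transcripts ankle day 3 had 48 and day 18 against day 7 had 11. Without blood day 3 replicate 1 and day 12 replicate 1, blood day 3 had 2559, day 12 had 308 and day 18 had 156. Without the 4 fluid arrays of other preparations fluid day 7 had 112.

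Leaving out each array in turn gave 0 to 4 changed genes at ankle day 1, 6 to 44 at day 3, 359 to 705 at day 7, 114 to 558 at day 12, 56 to 227 at day 18 and 0 to 7 for day 18 against day 7. In blood the range was 0 to 1100 at day 3, 0 to 2 at day 18 and 0 to 0 at days 1, 7 and 12. In fluid it was 145 to 229 at day 7, 141 to 200 at day 12 and 136 to 222 at day 18. It was 4432 to 5113 for fluid against blood, 2946 to 3375 for fluid against ankle and 111 to 227 for the interaction. Genes with signal near the negative controls, such as Cxcr2, are limited by background.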

Other observations

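The tests of other splits were planned before the data were examined, and the choice of the groups of genes described next was made after their values were seen. In the ankle, 2 of 7 erythroid genes fell at day 7 by either adjustment, the heme synthesis gene Alas2 (-2.05 ± 0.33, adjusted p = 0.000851) and the globin gene Hba-a1 (-1.54 ± 0.27, adjusted p = 0.00173). The list was not shifted (camera adjusted p = 0.19, downward), with a median of 0.03 and a mean of -0.48. At day 12 the same 2 of 7 fell by either adjustment, and the list was shifted downward (camera adjusted p = 0.0428), a call lost with an estimated correlation (adjusted p = 0.364). There Alas2 (-1.55 ± 0.36, adjusted p = 0.0207) lost its call without day 0 replicate 4 (adjusted p = 0.0746) or day 12 replicate 2 (0.175). Hba-a1 (-1.16 ± 0.30, adjusted p = 0.0363) lost it without day 0 replicate 3 (0.0937), day 0 replicate 4 (0.117), day 12 replicate 1 (0.0853) or day 12 replicate 2 (0.2). In fluid, 2 of 6 osteoclast genes rose at days 7 and 12 by either adjustment, without a shift of the list (camera adjusted p = 0.358 and 0.187), with a median of -0.12 and a mean of 0.48 at day 7. Cathepsin K, Ctsk, rose by 2.01 ± 0.32 (adjusted p = 0.00183) and 2.17 ± 0.34 (adjusted p = 0.00159), and the acid phosphatase gene Acp5 by 2.04 ± 0.37 at day 12 (adjusted p = 0.00426). At day 7 Acp5 rose by 1.497 (adjusted p = 0.0258) but not without day 3 replicate 1 (0.0679), day 3 replicate 2 (0.0754) or day 3 replicate 3 (0.115).

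Against blood, fluid cells had 6 of 7 erythroid genes lower (camera adjusted p = 0.015, and adjusted p = 0.113 with an estimated correlation) and all 4 platelet genes lower (camera adjusted p = 0.0151, and adjusted p = 0.148 with an estimated correlation), so that both calls were lost. Alas2 was lower by 3.50 ± 0.30 (adjusted p = 1.28e-10) and the platelet glycoprotein gene Gp1bb was lower by 0.98 ± 0.09 (adjusted p = 5.11e-10). Matrix degradation genes were higher in 10 of 13 cases (camera adjusted p = 1.19e-06), among them the lysosomal protease gene Ctsb (3.14 ± 0.11, adjusted p = 2.85e-19, 4 probe sets between 0.76 and 4.14). Complement and Fc receptor genes were higher in 8 of 12 cases against blood (camera adjusted p = 0.000204) and in 8 of 12 against ankle (camera adjusted p = 6.48e-07), with the anaphylatoxin receptor gene C3ar1 higher by 4.12 ± 0.16 (adjusted p = 5.87e-18) and 3.16 ± 0.16 (adjusted p = 2.58e-15). Of 6 osteoclast genes 2 were higher and 2 lower than in blood (camera adjusted p = 0.526), with Ctsk higher by 4.63 ± 0.15 (adjusted p = 5.58e-20). Of 6 eicosanoid genes 4 were higher and 1 lower than in blood (camera adjusted p = 0.0678), with Ltc4s higher by 1.82 ± 0.10 (adjusted p = 1.24e-14) and its other probe set by 0.16. The counts against blood were the same adjusted over the list alone, as was that of complement and Fc receptor genes against ankle. Against ankle 4 eicosanoid genes were higher and 1 lower, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.0254, lost at adjusted p = 0.0775 with an estimated correlation), with the cyclooxygenase gene Ptgs2 higher by 1.80 ± 0.21 (adjusted p = 3.53e-08).

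Other splits of the same arrays were counted for each comparison with at least 3 arrays per group. At ankle day 7 (555 changed genes) only the real 1 of 35 splits gave as many (highest other 201). The same held at ankle day 18 (166, highest other 145), ankle day 18 against day 7 (5, highest other 2) and fluid against ankle (3147, 1 of 100, highest other 1997). This is the smallest share possible, unadjusted over comparisons, and alone does not exclude chance. Chance cannot be excluded at ankle day 3 (19 genes, 2 of 35 splits, highest other 38). Nor can it at ankle day 12 (267, 2 of 35, highest other 702) or fluid day 7 (211, 2 of 35, highest other 548). For the ankle against the blood response splits cannot judge chance, as above. For blood at days 1, 3, 7 and 12 (0 genes each, 10 of 10 splits, highest other 0, 0, 0 and 1), fluid day 12 (223 genes, 1 of 10, highest other 0) and fluid day 18 (263 genes, 1 of 10, highest other 0) the splits are too few for a share under 0.05.

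The highest other splits at ankle days 3, 12 and 18 each set replicates 1, 3 and 4 of day 0 against replicate 2 with the later arrays. That of day 12, with 702 genes against 267, points to a structure of the samples in which day 0 replicate 2 lies toward the later arrays. The highest other split of fluid day 7, with 548 genes against 211, followed the preparation, with the 4 arrays taken during dissection on 1 side, and points to a structure of the samples as well. Within that preparation 112 genes passed at fluid day 7. With replicate numbers as a block, in a fit of all 13 fluid arrays, 199 passed. Where replicate numbers paired the samples, the 8 splits that part as many pairs gave at most 0 genes apart from the real one for ankle day 3 and at most 8 for fluid day 7. For blood days 1 and 3 the 4 such splits gave 0.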
